A study of Homo sapiens with 9 samples.

How the data were processed

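RNA from 9 samples of MEC-1, an established human B cell line derived from a chronic lymphocytic leukemia, was measured on 1-colour expression arrays. Per the labels' protocols, biotin-labelled cRNA was made from 200 ng of total RNA by the array maker's standard procedure, after 2 h of starvation in medium with 0.1% serum. The titles place 4 samples in the Control group, whose cells had basal MMP-9, and 5 in the MMP-9 group, and call each a biological replicate. The array model, the gene definition behind its probes and the genome build are not given in the sources used here.

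The deposited table holds log2 expression values, 1 row per Ensembl gene ID and 1 column per array. Per the submitters' processing notes, the authors processed the arrays with RMA, which corrects background, normalizes between arrays and summarizes probes. No RMA version is stated there. RMA forces the arrays to nearly equal distributions, so a change shared by most genes would not be seen in these values, and low genes have compressed fold changes. The table has 24916 rows and 9 columns, all of them mapped to a sample by the accession in the column name. No probe intensities or detection calls were used here, so no gene could be called absent, and "near the floor" below refers only to the lowest 25% of gene levels. The number of arrays, not a read depth, limits the precision.

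The files do not pair Ensembl IDs with gene names: the reference table used here lists 0 Ensembl IDs. Gene symbols are therefore not given. The 30 gene lists written in advance, the tests of MMP9 and CD99 by name, and the passing over of gene kinds in the rule for named genes could not be applied and were not run. The rule took genes with adjusted p under 0.05, no overlap between the groups and a mean in the higher group at or above the median level, ordered by the size of the change. It was applied to the first 2 IDs in each direction.

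The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 24916 genes, threshold 0.05), with all 9 arrays as independent samples, no filter on low values and no covariate. Fold changes are MMP-9 over Control on the log2 scale. The alternatives chosen before the data were examined were the replicate number as a block, quantile normalization again, centring on the median, a trended robust prior, array weights, omission of genes under the median level, a plain t-test with equal variances, and omission of each of the 9 arrays. The alternatives about several probe sets per gene did not apply, since each ID has 1 row.

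Arrays that share a replicate number deviated together. The correlation of their deviations from the group means over all genes was 0.62 for number 1, 0.15 for number 2, 0.17 for number 3 and 0.32 for number 4. Some arrays of unlike number correlated more: Control replicate 3 with MMP-9 replicate 4 at 0.44, and Control replicate 4 with MMP-9 replicate 5 at 0.36. The labels do not say what a number stands for, so the pairing comes from the numbers in the titles and from these correlations, and the blocked counts stand beside the main ones. The correlations and the blocked counts were first computed together, and the pairing was decided by a set bound of 0.1 on every correlation. Some arrays of unlike number also passed that bound, so it cannot establish that the numbers mark pairs. MMP-9 replicate 5 has no Control array of its number, so the blocked fold changes are the same as those without that array. The blocked fit has 3 residual degrees of freedom against 7. It takes no account of the correlations between arrays of unlike number, and no other fit blocked on them across the groups.

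After the data were seen, alternatives for 3 close pairs of arrays (same group, Pearson r above 0.995) were added: each pair as a random block (duplicateCorrelation, consensus correlation 0.69), and each pair averaged to 1 replicate, which leaves 6 replicate units, 3 per group. Also added were the count of genes past the limma threshold and near the floor in 1 group (group mean at or below 5.20, the 25 percentile of gene means, with the other group at or above 6.69, the median) and 3 groups of cell cycle IDs. Each cell cycle group is the 60 measured IDs ranked highest in the human phase marker pairs distributed with the scran package, by the times an ID is the higher member of a pair minus the times it is the lower. This form was kept after others had been tried: every higher member of a pair (1063 to 1103 measured IDs a phase), IDs never the lower member (78 to 90), and the top 30 and top 100 of the same ranking. The choice was made on how strongly the members correlated within the groups of arrays, so that correlation is no independent evidence for the groups. Median changes had been seen only for every higher member. The results of each form are given with the alternatives. The groups were tested with camera (preset correlation 0.01, and estimated, both in 17 fits), fry (9 independent arrays only), and a two-sided exact permutation test of array means over all 126 splits.

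The fits were tested on simulated data: the 24916 genes with their observed means and moderated spreads, 200 of them changed, 50 at each of 4 fold sizes. With independent arrays the main fit called 183 genes, 11 of them unchanged (6.01%), and recovered 30 of 50 genes at 1.5-fold, 43 at 2-fold, 50 at 4-fold and 49 at 8-fold. With a simulated correlation of 0.7 within close pairs, the main fit called 89 unchanged genes among 267 (33.3%). The fit with the pair as a random block called 8 among 175 (4.57%), and the fit on pair averages 11 among 174 (6.32%). Genes were drawn independently, and arrays of different groups had no likeness beyond the gene means. The real arrays do have such likeness, so these false shares may not carry over to them.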

Results

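Gene expression was measured in MEC-1 cells, an established B cell line derived from chronic lymphocytic leukemia, after lentiviral transfer of a GFP vector. In the MMP-9 group (5 arrays) the vector also carried DNA for proMMP-9, the inactive precursor of matrix metalloproteinase-9, a secreted gelatinase. In the Control group (4 arrays) MMP-9 was at its basal level. The comparison asks which transcripts differ between cells that overexpress MMP-9 and their controls. Values are log2 RMA expression of 24916 genes, known here by Ensembl ID only. Array medians lay between 6.65 and 6.72, lower quartiles between 5.17 and 5.22 and upper quartiles between 9.01 and 9.07.

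Between the groups, 71 genes were higher in MMP-9 cells and 135 were lower (limma, adjusted p under 0.05). Lower genes differed more: their median change was -1.22 on the log2 scale (2.32-fold), against 0.74 (1.67-fold) for higher genes. Of the higher genes, 47 differed by 1.5-fold or more, 23 by 2-fold, 10 by 4-fold and 1 by 8-fold. Of the lower genes, 114 differed by 1.5-fold or more, 81 by 2-fold, 35 by 4-fold and 9 by 8-fold. The median change of all genes was 0.0026. The 71 higher and 135 lower genes all had groups that did not overlap, as did 1053 of all genes (4.23%). Chance gives 1.59% if the 9 arrays are independent. The close pairs described below can raise that share, so an excess over chance is not shown.

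These counts rest on treating the 9 arrays as independent. With the replicate number as a block, 16 genes were higher and 27 lower, of which 13 and 23 were also called without it. With the 3 close pairs described below as a random block, 18 genes were higher and 61 lower, all among those called without it. With each close pair averaged to 1 replicate, 4 were higher and 12 lower. Array weights gave 511 higher and 631 lower genes, and the plain test with equal variances gave 19 and 47. A set of 8 higher and 20 lower genes was called with independent arrays, with the replicate block and with the close pair block alike. Of these, 3 higher and 11 lower genes were also called on pair averages. No fit here models likeness across the groups between arrays of unlike number, so this set is not free of it. The 9-array total of 206 genes became 542 without Control replicate 2, 92 without Control replicate 3, 71 without Control replicate 4, 108 without MMP-9 replicate 2, 99 without MMP-9 replicate 3, 113 without MMP-9 replicate 4 and 114 without MMP-9 replicate 5. In every fit that left out 1 array, 16 higher and 48 lower genes stayed past the threshold.

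**Figure D1:**
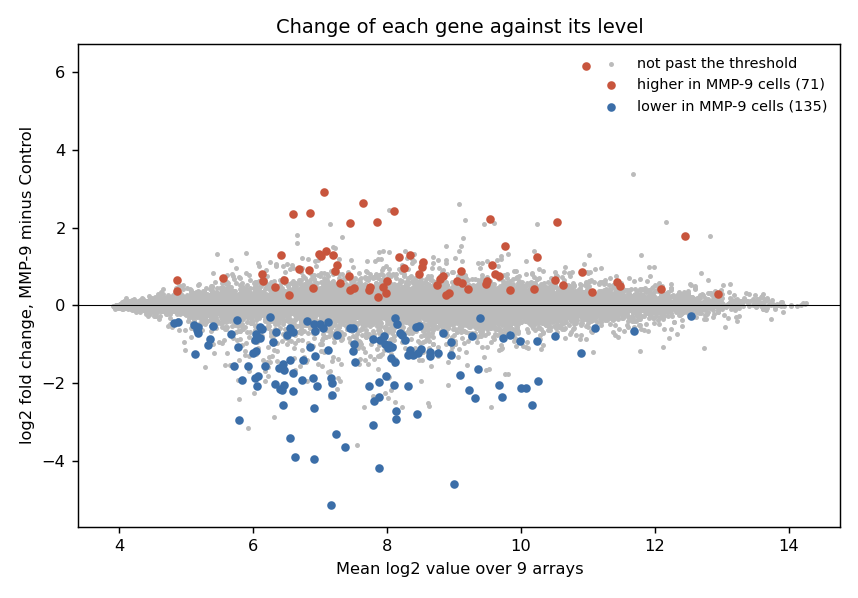
The log2 fold change of each gene (MMP-9 minus Control, y axis) is plotted against its mean log2 value over the 9 arrays (x axis), with genes past the limma threshold in colour. The 71 higher and 135 lower genes lie at all levels, and 1 higher gene stands apart at 6.16.

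The largest increase was that of ENSG00000100985. Its log2 value was 7.54 ± 0.44 (SD, n = 4) in Control and 13.70 ± 0.08 (SD, n = 5) in MMP-9 cells, a 71.5-fold difference (log2 fold change 6.16, SE 0.18, limma adjusted p = 1.73e-06). Its limma adjusted p ranged from 7.51e-09 to 0.0087 over the alternatives, with the highest on pair averages. Since IDs were not paired with names, it was not checked whether this is the gene that the vector carried. ENSG00000227124 had the next largest increase under the rule, from 5.44 ± 0.17 to 8.35 ± 0.45 (SD, n = 4 and 5), or 7.53-fold (log2 fold change 2.91, SE 0.22, limma adjusted p = 0.0007). It did not pass the threshold on pair averages (limma adjusted p = 0.075, the highest of its alternatives, whose lowest was 0.00021).

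The largest decrease was that of ENSG00000198692, from 10.02 ± 0.27 (SD, n = 4) in Control to 4.89 ± 0.16 (SD, n = 5) in MMP-9 cells, where it lay in the lowest 25% of gene levels. Control exceeded MMP-9 cells 35.1-fold (log2 fold change -5.13, SE 0.13, limma adjusted p = 1.73e-06, and from 2.24e-07 to 0.0035 over the alternatives). RMA compresses values this low and no detection call was used, so this measured fold can understate the difference. Its chromosome was not looked up, and sex-linked genes, which the rule passes over, could not be recognized without a table. ENSG00000150637 differed from 11.55 ± 0.17 to 6.95 ± 1.02 (SD, n = 4 and 5), 24.1-fold (log2 fold change -4.59, SE 0.47, limma adjusted p = 0.0045). It lost the call with the replicate number as a block (limma adjusted p = 0.059) and on pair averages (limma adjusted p = 0.21), where the lowest of its alternatives was 0.00088. The MMP-9 arrays spread from 5.37 to 7.90 for this gene, all below the lowest Control value of 11.30.

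**Figure D2:**
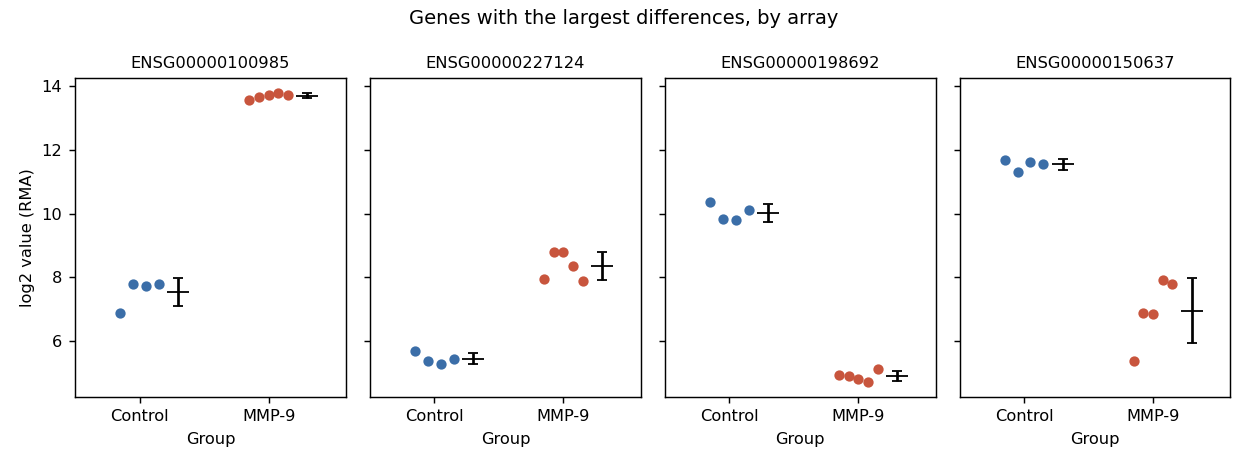
Points are log2 RMA values of single arrays (y axis) by group (x axis) for the 2 genes with the largest increase and the 2 with the largest decrease under the rule, and bars are the mean and SD of 4 Control or 5 MMP-9 arrays. The groups do not overlap for any of the 4 genes, and Control replicate 1 sits below the other Control arrays for ENSG00000100985 (6.89).

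The 24916 genes were divided into 4 classes of 6229 by their mean over the 9 arrays, a mean to which the changes themselves contribute. The lowest class held 2 higher and 7 lower genes. The next class held 9 higher and 40 lower, and the class above it, with means from 6.69 to 9.03, held 35 and 67. In the top class, with means of at least 9.04, 25 genes were higher and 21 lower. By level alone, 13 genes lay at or above the median level in Control and in the lowest 25% of levels in MMP-9 cells, and 7 of these passed the limma threshold, with a median of 8.45 against 4.99. By level alone, 0 genes met the reverse criterion. The 7 were all called with the close pairs as a random block, and 4 with the replicate number as a block or on pair averages. Whether these genes share a chromosome or are sex-linked was not examined. Without Control replicate 2 the same criteria, the threshold included, took 12 genes. This group was defined after the data were seen.

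The arrays of a group were not equally far apart. Control replicates 3 and 4, MMP-9 replicates 2 and 3, and MMP-9 replicates 4 and 5 each correlated at 0.997 to 0.998 over all genes. The other 13 pairs within a group correlated at 0.984 to 0.991, and the 20 pairs across groups at 0.978 to 0.990. Of the sum of squares over all genes, 31.7% lay between the groups, 60.9% between replicate units of a group and 7.37% between the arrays of a close pair. These parts had 1, 4 and 3 degrees of freedom, with mean squares summed over genes of 4330, 2078 and 335. The part between the groups thus also holds spread between replicate units, and is not a share due to MMP-9. The labels call all 9 samples biological replicates and do not say which cultures they came from, so p-values that treat the close pairs as independent may measure partly technical spread.

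**Figure D3:**
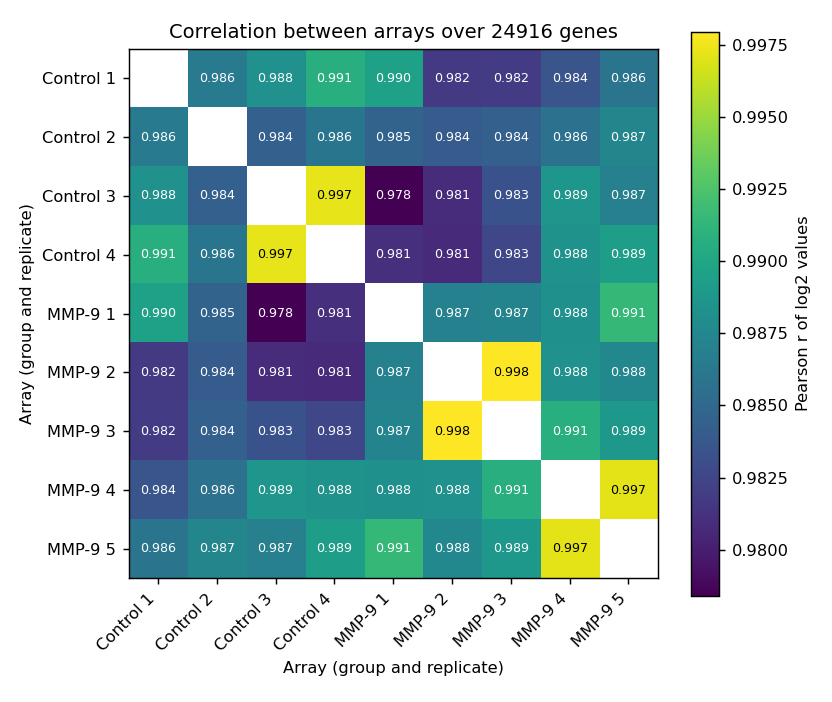
Each cell gives the Pearson correlation of log2 values over 24916 genes between 2 arrays, named on both axes by group and replicate. The 3 close pairs, at 0.997 to 0.998, stand above all other pairs, whose highest value is 0.991.

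**Figure D4:**
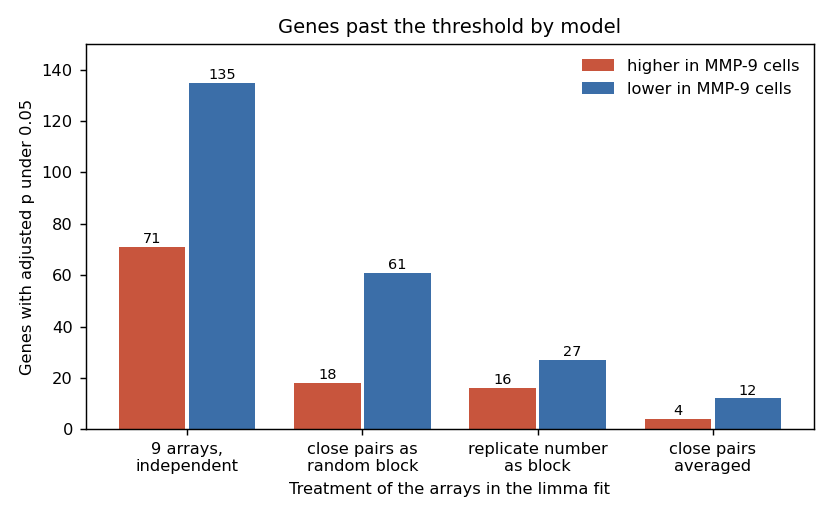
Bars give the number of genes past the limma threshold (y axis, from 0) that were higher or lower in MMP-9 cells under 4 treatments of the arrays (x axis). The counts go from 71 higher and 135 lower with independent arrays to 4 and 12 on pair averages, and lower genes outnumber higher genes in each.

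Groups of cell cycle genes were compared because they could be tested by ID. Of 60 IDs each for G1, S and G2M, 0 passed the limma threshold in any group, over all genes or adjusted over the list alone. At an unadjusted limma p under 0.05 there were 8 G1, 5 S and 3 G2M members, against 2640 of all 24916 genes. The plain test with equal variances gave 7, 5 and 0 unadjusted, against 2365 of all genes, and 0 adjusted. The median log2 change was -0.04 for G1, -0.07 for S and -0.10 for G2M, with 33, 39 and 40 of 60 members below 0. Camera with its preset correlation gave adjusted p = 0.37, 0.069 and 0.20 over the 3 groups, and adjusted p = 0.66 for each with an estimated correlation. With the replicate number as a block, the S group had a median of -0.11 (limma camera adjusted p = 0.014, preset correlation), and adjusted p = 0.59 with an estimated correlation. Its preset-correlation value also passed without MMP-9 replicate 1 (median -0.09, limma camera adjusted p = 0.015) or MMP-9 replicate 4 (-0.09, limma camera adjusted p = 0.016). It passed without MMP-9 replicate 5 too (-0.11, limma camera adjusted p = 0.014). The blocked fold changes are those without that array, so these 2 results are not separate support. The S group median was nearer 0 without MMP-9 replicate 2 (-0.01, limma camera adjusted p = 0.58) or MMP-9 replicate 3 (-0.03, limma camera adjusted p = 0.24). The S group means of these 2 arrays, -0.24 and -0.19, lay below those of the other 7 arrays (0.03 to 0.09). The preset-correlation value of the G2M group passed without MMP-9 replicate 1 (median -0.14, limma camera adjusted p = 0.020). With an estimated correlation, 0 of the 3 groups passed in any of the 17 fits in which camera was run (limma camera adjusted p from 0.46 to 0.99). By array, the mean deviation of the G2M group from its overall mean was 0.06 ± 0.11 in Control (SD, n = 4) and -0.05 ± 0.30 in MMP-9 cells (SD, n = 5), a difference within the spread (two-sided exact permutation p = 0.48, adjusted 0.59). The S group gave an exact permutation p of 0.42 and the G1 group 0.59, both adjusted to 0.59.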

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

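One of the 20 sets of replicate values that were examined held a sample far from the others of its group, which is what chance alone gives in about 1 of 20. ENSG00000100985, the gene with the largest increase, had a log2 value of 6.89 in Control replicate 1, against 7.72 to 7.79 in the other Control arrays. Without that array its log2 fold change was 5.94 (limma adjusted p = 7.51e-09), and without any other single array it was at most 6.24 (highest limma adjusted p = 3.43e-05).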

How the results depend on the processing

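The close pair settings and the cell cycle groups were chosen after the data were seen. For the 9-array counts of 71 higher, 135 lower, 47 higher and 114 lower by 1.5-fold or more, and 7 called genes near the floor in MMP-9 cells, the replicate block gave 16, 27, 15, 27 and 4. Close pairs as a random block gave 18, 61, 18 and 58. Close pairs averaged gave 4, 12, 4, 12 and 4. Array weights gave 511, 631, 249, 395 and 11, and the cause was not tested. The plain t-test with equal variances gave 19, 47, 15 and 41. Leaving out 1 array gave 17 to 215 higher, 54 to 327 lower, 16 to 160 and 50 to 251 by 1.5-fold or more, and 6 to 12 near the floor. Lower genes outnumbered higher genes in all of these fits. Normalization, centring, the trended prior and the omission of low genes kept the counts of higher and lower genes within 1.5 times. Normalization and centring moved the fold change of a gene by a median of only 0.0060 and 0.0034, so they test nothing. The omission of low genes gave 2 genes near the floor, since it drops genes by their mean over all arrays. Normalization, centring and the trended prior each gave 7. Of 72 refits of the 4 named IDs, 69 kept direction and call, 3 lost only the call and 0 turned. The replicate block moved the S group past the threshold (median -0.11, limma camera adjusted p = 0.014), as did quantile normalization (-0.0797, limma camera adjusted p = 0.024) and omission of low genes (-0.0824, limma camera adjusted p = 0.040), which also moved G2M (-0.110, limma camera adjusted p = 0.049). Leaving out 1 array gave S medians from -0.110 to -0.0132 and G2M medians from -0.170 to -0.0135, where S passed without MMP-9 replicate 1, 4 or 5 and G2M without MMP-9 replicate 1. The replicate block and the fit without MMP-9 replicate 5 have the same fold changes, so they are not separate support. All these values use camera's preset correlation. With an estimated one, 0 groups passed in the same fits (limma camera adjusted p from 0.46 to 0.99). Fry was run on the 9 independent arrays only (limma fry adjusted p = 0.72). None of the other forms of the cell cycle groups that were tried passed as a group: limma camera adjusted p was 0.56, 0.14 and 0.14 for G1, G2M and S with the top 30, 0.45, 0.41 and 0.052 with the top 100, 0.59 with IDs never the lower member, and 0.22 with every higher member. Called members numbered 0 with the top 30 or top 100, 1 in G1 and 0 in S and G2M with IDs never the lower member, and 5 in each phase with every higher member. The G1 median was above 0 with the top 30 (0.02). The 2 alternatives about probe sets and the gene lists were not run.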

Other observations

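The tests of the close pairs, of their share in the excess of lower genes, and, for the floor genes, of genes of like level, of pair averages and of differences within replicate numbers were chosen after those results were seen. The floor genes and the cell cycle groups were themselves defined after the data were seen, and the other tests were written before their results. The cell cycle groups varied more between arrays of the MMP-9 group than between the groups. The mean deviation of the G2M group was -0.43 and -0.31 on MMP-9 replicates 2 and 3, which form a close pair, and 0.20, 0.15 and 0.15 on MMP-9 replicates 1, 4 and 5. The 4 Control arrays lay between -0.06 and 0.16. The S group was at -0.24 and -0.19 on the same 2 arrays and between 0.06 and 0.09 on the other 3. The G2M members also moved together within groups (mean correlation 0.27, against at most 0.06 in 1000 random groups of 60 IDs), the S members less (0.12) and the G1 members least (0.07). These correlations guided the choice of the groups; of the forms not kept, IDs never the lower member gave 0.045 for G2M, and the top 30 gave 0.42. In 71 of 100 splits of the arrays, camera with its preset correlation gave a G2M p at least as small as the real 0.14, down to 8.81e-15, and 60 of the other splits gave an unadjusted p under 0.05, so chance cannot be excluded for G2M and that setting is too liberal here.

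In 100 of the 126 splits of the 9 arrays into 4 and 5, 2 gave as many higher genes as the real 71, 2 as many lower genes as the real 135 and 2 as many higher by 1.5-fold or more as the real 47, the real split included each time. The highest other values were 256, 177 and 107. They came from the split that set Control replicates 3 and 4 and MMP-9 replicates 4 and 5 against the rest, with 433 genes in all against the real 206, which points to a structure of the samples across the groups. Only 12 of the drawn splits kept all 3 close pairs together, and 2 of these gave as many genes as the real one, so the share of 2 in 100 excludes chance only for arrays that are independent. The 13 drawn splits that parted all 4 number pairs gave 0 genes apart from the real one. For genes lower by 1.5-fold or more the real 114 was reached in 1 split, the real one, with 65 as the highest other. A split that mixes the groups has no set direction, and the one with 433 genes had 65 in this direction and 107 in the other. Its genes past 1.5-fold in both directions together outnumber the real 47 and 114 together. The limit from the close pairs holds for this count too. In 1 split, the real one, there were as many called genes near the floor in MMP-9 cells (7 against 0 in the others), but the criteria were set after the real groups had been seen, so this does not exclude chance. By level alone the real split gave 13 such genes, and the other splits gave up to 5 in the group of 5 arrays and up to 10 in the group of 4. With close pairs averaged, the real split gave 16 genes and the other 9 of 10 splits gave 0, so that 1 split was as large, too few splits for a share under 0.05.

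The 3 close pairs of arrays may be single cultures or extracts measured on 2 arrays, or pairs that shared a batch. The median over genes of the mean square within pairs over that between replicate units was 0.24. Since the pairs were picked for being close, this value cannot decide, and a pair of cultures grown side by side stays open as well. The labels give no date or batch.

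More genes were lower than higher in MMP-9 cells (65.5% of calls). The close pairs stay open as a cause. Lower calls made up 75% on pair averages and 77.2% with the pair as a random block. Both fits call fewer genes, and lower genes differed more, so a higher share could follow whatever the cause. The plain t-test with equal variances, which also calls fewer genes but ignores the pairs, gave 71.2%. The authors' normalization stays open: quantile normalization again and median centring left a share of at least 65.1%, but moved the fold change of a gene by a median of only 0.0060 and 0.0034, so they test nothing. With array weights the share was 55.3%. A biological difference between the cell groups, and a difference between separately transduced cell populations that has no link to MMP-9, stay open and untested.

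The 7 called genes near the floor in MMP-9 cells alone had values no higher than 5.35 on any MMP-9 array, and the median of their log2 changes was -3.41. Genes of like level did not move with them: the 200 genes nearest in Control level to each had a median change of 0.015 (SD 0.38). Of these 1400, 0 fell as far as the median of the 7. The lowest was -3.31, farther than some of the 7 (from -5.13 to -1.91). The 7 were picked for falling and their neighbours were not. The values therefore argue only against a normalization shift common to genes of that level. A batch that shares a number would fall on both groups alike. All 28 differences within the 4 shared numbers were below 0 (from -5.42 to -0.93). For the 7 as picked, every Control value lay above every MMP-9 value. Any pairing of arrays would give this sign, so it cannot decide. With the number as a block, 57.1% passed, with 3 residual degrees of freedom in place of 7. The median change was then -3.45, as it was without MMP-9 replicate 5, whose number has no Control array. Each other number holds 1 array of each group, so the block could not shrink the change. The block therefore cannot decide, and such a batch stays open. Dependence within close pairs is argued against only in part: 100% passed with the pair as a random block but 57.1% on pair averages (4 residual degrees of freedom, median change -3.51), and it stays open for the other 3 genes. A hypothesis, not tested since gene positions were not used here, is that the MMP-9 population lost or silenced a set of loci, or a chromosome, when it was transduced or selected.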
